A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

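Budding yeast cells (Saccharomyces cerevisiae) grown in synthetic medium at 30 °C to stationary phase were profiled on 3 single-colour Affymetrix arrays. Per the labels, 2 arrays hold RNA of cells without RPA12 and 1 array holds RNA of wild-type cells, and all 3 are described as the haploid laboratory strain BY4741, of mating type a, with changes in HIS3, LEU2, MET15 and URA3. Per the labels' protocols, 6 µg of total RNA was converted to biotinylated cRNA for each array. The growth protocol given for the wild-type array names cells lacking RPA12, as it does for the other arrays, while its description and genotype read wild type, and those were followed.

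The deposited values are log2 probe-set summaries that the authors made with RMA, per the submitters' processing notes, which also name Affymetrix Expression Console. Versions and the set of arrays that went into a single RMA run are not given in the sources used here. RMA subtracts background, forces the probe intensities of all arrays in a run onto one distribution, and combines the probes of a set, so a change of most transcripts in one direction would be hidden and small differences near the floor are compressed. The deposited values were used as they stand, without further normalization. Of 10928 probe sets, 7244 had a single gene symbol in the platform annotation, 1 had several genes and was not named, and 3683 were not listed. Of those with a single symbol, 5498 belonged to S. cerevisiae genes (5449 genes) and were tested, and 12 symbols were updated through their gene identifiers with the RefSeq gene table of assembly R64, which was used only for names and for which genes are neighbours. The other 1746 carry symbols of another yeast species that the array also covers, and served as background. The probe sets not listed comprise 213 array controls and 3470 without a name here.

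The background level of an array was the value under which 95% of the background probe sets lay, which was 1.42 on each array labelled RPA12 deletion and 1.84 on the wild-type array. A probe set at or below it on every array of a group has only a bound there, and its fold is given as "at least", computed with the dim group's values raised to that level. Above the level were 96.9%, 96.9% and 93.3% of the tested probe sets. The number of arrays, and not a read depth, limits the precision.

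Differences are the mean of the 2 arrays labelled RPA12 deletion minus the wild-type array, on the log2 scale. The test was limma (version 3.58.1, in R 4.3.3), lmFit and eBayes, two-sided, with Benjamini-Hochberg adjusted p under 0.05. With a single wild-type array the spread comes from the 2 other arrays (1 residual degree of freedom per probe set), and the lone array is assumed to vary alike. Nothing in the labels says that the 2 arrays came from separate cultures, so p-values measure only the spread between them, which may be technical. Their values were equal to every deposited digit for 2431 tested probe sets (44.2%). In data simulated for this comparison with 5498 genes and such ties, limma called 46.2% of 5298 unchanged genes (2448). None of them was also at least 2-fold apart. All simulated arrays, the wild type included, had a noise SD of 0.057, taken from the spread between the 2 arrays labelled RPA12 deletion. A 2-fold difference could hardly arise from such noise, so the simulation does not test the 2-fold rule. Without ties limma called 0.23%. With the ties, it called 43 of 50 genes changed by log2 1 and 49 of 50 changed by log2 2. For that reason "rose" and "fell" are used only for a probe set with limma adjusted p under 0.05 and a difference of at least 2-fold, an alternative listed before the data were examined. The choice to word the text by it was made after the ties were seen.

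Before the data were examined, 46 gene lists were fixed. Of these, 39 were tested with camera in limma (correlation between genes preset at 0.01, 1 probe set per gene, the highest mean over the 3 arrays), and 7 lists of markers, neighbours and single genes were described only. Camera was also run with an estimated correlation. That estimate rests on 1 residual degree of freedom and has little power. A list that it does not call stays undecided. In simulated data with ties, camera gave p under 0.05 for 14 of 500 random lists of 25 unchanged genes. The simulated genes varied independently, so this does not cover lists whose members vary together. Each list's median was also placed among 10000 random lists of the same size and matched mean level. The genes named are the 12 largest rises and the 12 largest falls among probe sets past the limma threshold, with both arrays labelled RPA12 deletion at least 2-fold from the wild type on the same side, a single gene name, and the brighter group above background. In each list, up to 4 members with the largest differences are named, and all members of lists of up to 6 genes and of the single genes. Genes named outside this rule are said to be so. Many ribosomal protein genes and other families have near-identical copies, whose probe sets can share signal.

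The alternatives were quantile normalization again over the tested probe sets, median centring, a filter on dim probe sets, an intensity trend, robust eBayes, treat against a 1.5-fold change, 1 probe set per gene, a 2-fold minimum, each array labelled RPA12 deletion left out, and for lists ranks, fry, the mean over probe sets and an estimated correlation. Chosen after seeing the data were a fit to probe sets with unequal values, a variance pooled over probe sets, and centring or leaving out an array for the list medians. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.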

Results

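Steady-state transcript levels of stationary-phase yeast were compared between cells labelled as lacking RPA12, which encodes a small subunit of RNA polymerase I, the enzyme that transcribes ribosomal RNA genes, and cells labelled wild type. There were 2 arrays labelled RPA12 deletion and 1 wild-type array, each giving log2 RMA values for 5498 tested probe sets. The median value was 5.74 on each of the arrays labelled RPA12 deletion and 5.49 on the wild-type array.

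The targeted gene went against its label. RPA12 read 5.74 and 5.79 on the arrays labelled RPA12 deletion and 3.60 on the wild-type array, a difference of 2.16 (limma adjusted p = 0.0090), so its signal was 4.48-fold higher where the gene is labelled absent, and 2.91-fold higher after quantile normalization again. All of these values lie above the background levels of 1.42 and 1.84. Its neighbours on the chromosome were closer to equal, with NTA1 at 4.52 and 4.52 against 4.67, and CCT5 at 7.69 and 7.62 against 7.03, and their median difference of 0.24 changes sign under median centring. Where in the gene the probes of the RPA12 set lie is not given in the sources used here, and a probe outside the deleted part would not check the label. Every direction below is that of the arrays labelled RPA12 deletion relative to the wild-type array, with this mismatch standing.

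Several genes that differ between laboratory strains and mating types differed strongly, while others were nearly equal. MET17, also known as MET15, which encodes an enzyme of sulphide assimilation and is described as deleted in the labelled background, read 9.40 ± 0.047 (SD, n = 2) on the arrays labelled RPA12 deletion and was not above background on the wild-type array at 1.56, at least 188-fold higher (limma adjusted p = 0.0025). LYS2, an enzyme of lysine synthesis, was not above background on the arrays labelled RPA12 deletion at 1.42 and 0.97 and read 6.08 on the wild-type array, at least 25.3-fold lower (limma adjusted p = 0.0302). On the first of these arrays LYS2 lay exactly at the background level. Of 5 measured α-specific genes, 4 rose and none fell, with a median difference of 4.74. MF(ALPHA)1, which encodes the α-factor pheromone, rose at least 130-fold. HMLALPHA1, whose sequence is also found at the mating-type locus of α cells, rose at least 37.4-fold. STE3, the receptor for a-factor, read 6.85 ± 0.059 (SD, n = 2) against 2.11, and MF(ALPHA)2 read 3.57 on both arrays against 2.01, a difference of 1.56 that became 0.99, under 2-fold, after quantile normalization again. SAG1, at 6.13 ± 0.072 (SD, n = 2) against 5.33, was under 2-fold apart. HMRA1, whose sequence is also found at the mating-type locus of a cells, fell at least 63.6-fold, from 7.41 to 1.17 ± 0.12 (SD, n = 2).

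The a-specific genes went in both directions. Of 7 measured, 2 rose (ASG7, from 3.17 to 4.37, and BAR1, from 2.58 to 3.65) and 1 fell (MFA2, an a-factor gene, from 8.26 to 6.06 ± 0.069, SD, n = 2). After quantile normalization again the differences of ASG7 and BAR1 were 0.31 and 0.18, under 2-fold. MFA1, the other a-factor gene, read 6.85 ± 0.061 (SD, n = 2) against 7.45. STE2, the receptor for α-factor, read 6.37 on both arrays labelled RPA12 deletion and 5.61 on the wild-type array. The median difference of this list was 0.13, which becomes negative under each other scaling. Of 14 haploid-specific and pheromone-induced genes, 9 rose and 1 fell, with a median of 1.37. AGA1, the anchor of the a-agglutinin, rose at least 36.9-fold, KAR4, a mating transcription factor, 32.3-fold, PRM1, a protein of mating cell fusion, at least 17.9-fold, and FUS1, another, 19.4-fold. Of 20 meiosis and sporulation genes, 2 rose and 4 fell (median -0.03), among them IME2 at a difference of 3.84, SSP1 at 1.99, and SPO13, not above background on the arrays labelled RPA12 deletion and at least 2.12-fold lower, while DIT1 at 1.46 did not pass (limma adjusted p = 0.0548). Of the 4 genes described as changed in the labelled background, whose median difference was 1.28, HIS3 read 9.28 ± 0.023 (SD, n = 2) against 6.73, LEU2 1.75 on both arrays against 1.91, and URA3 1.25 on all 3 arrays.

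**Figure D1:**
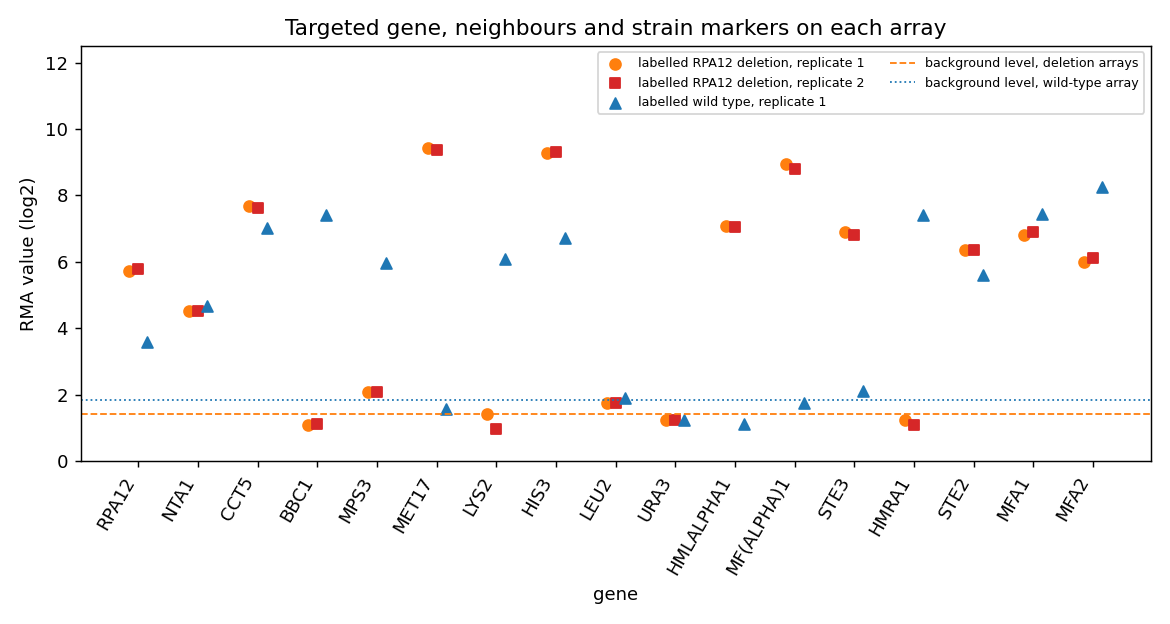
RMA values (log2, vertical axis) of the targeted gene, its neighbours, strain and mating-type markers, and the gene pair BBC1 and MPS3, one point per array, with dashed and dotted lines at the background levels. RPA12 lies higher on the arrays labelled RPA12 deletion (5.74 and 5.79) than on the wild-type array (3.60), while MET17, HMLALPHA1, LYS2, HMRA1 and BBC1 are at background on one side.

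Across the transcriptome, ribosome-building and sulphur-assimilation genes were higher on the arrays labelled RPA12 deletion, and genes of gluconeogenesis, respiration, the general stress response and stationary phase were lower. Camera called 3 lists higher and 7 lower of 39, and none with an estimated correlation, where the smallest adjusted p = 0.68. With 1 residual degree of freedom the estimated correlation leaves little power, so the loss of these calls decides little. With limma adjusted p under 0.05 and at least 2-fold, 1310 probe sets rose and 562 fell, and without the test 1340 were at least 2-fold higher and 603 at least 2-fold lower. The 2 arrays labelled RPA12 deletion differed from each other with an SD of 0.08 and had no probe set 2-fold apart, while each differed from the wild-type array with an SD of 1.29 and 1.28 and had 1948 and 1944 probe sets 2-fold apart. The correlation across probe sets, which are not independent replicates, was 0.999 within the group and 0.797 and 0.80 against the wild type. Background probe sets differed from the wild-type array with an SD of 0.27 each. By limma's adjusted p alone, 2773 probe sets were higher and 1634 lower, which includes differences down to 0.0026 on the log2 scale and the ties described under the methods. The median of all tested probe sets was 0.19 higher, and another scaling moved it by -0.26 (quantile normalization again) or -0.25 (median centring). The higher share of limma's calls was 62.9%, against 46.2% and 47.5% under those scalings, and the higher share of 2-fold differences was 69.0%, against 52.4% and 55.9%, so the balance of higher against lower is not settled. The array controls also set the groups apart: 36 poly-A spike-in probe sets, from transcripts added to the RNA before labelling, had a median difference of -3.81, and 27 hybridization controls one of -1.48, so array processing and group cannot be told apart.

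Beyond MET17 and the mating genes, the largest rises were in MET16, HXT1 and TRP3. MET16, an enzyme of sulphate reduction, rose 62.4-fold to 7.90 ± 0.051 (SD, n = 2), and HXT1, a low-affinity glucose transporter induced by abundant glucose, rose 36.6-fold to 7.70 ± 0.013 (SD, n = 2). TRP3, of tryptophan synthesis, rose 32.3-fold. IRC7 rose 29.2-fold, ETT1 28.8-fold and YCH1 27.5-fold. With HMRA1, the largest fall was in BBC1, a protein of cortical actin patches, from 7.41 to 1.11 ± 0.017 (SD, n = 2), which is not above background and at least 63.5-fold lower (limma adjusted p = 9.43e-04). TIS11, which degrades messenger RNAs when iron is short, fell 60.9-fold, GRE1, a hydrophilin of the stress response, 53.5-fold, and NCA3 52.8-fold. YOR387C fell 41.2-fold, STL1, a glycerol transporter, 36.1-fold, and YKL107W 27.5-fold. SSA3, a stress-induced Hsp70, fell 27.5-fold, ALD6, a cytosolic aldehyde dehydrogenase, 27.4-fold, and PDC6, a minor pyruvate decarboxylase, 26.6-fold. The limma adjusted p of these 24 genes lay between 7.70e-04 and 0.0315.

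**Figure D2:**
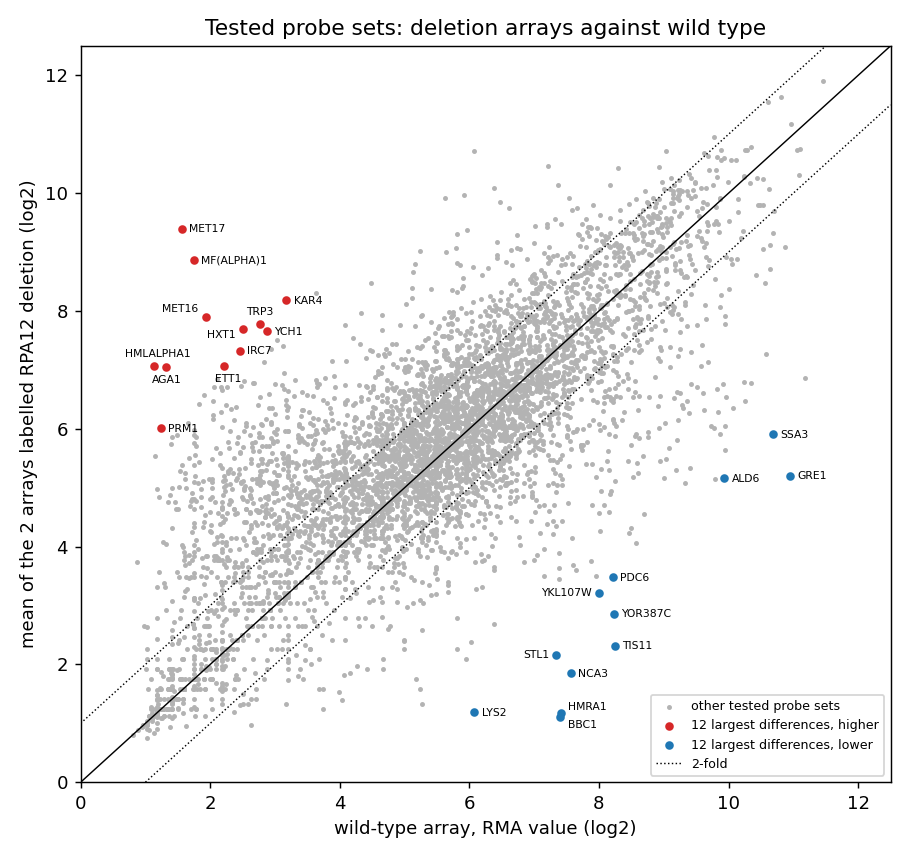
Mean log2 RMA value of the 2 arrays labelled RPA12 deletion (vertical axis) against the wild-type array (horizontal axis) for the 5498 tested probe sets, one point each, with the line of equality and dotted lines at 2-fold. The 12 largest rises and 12 largest falls are named, among them MET17 (9.40 against 1.56), and BBC1 and HMRA1 (each 7.41 on the wild-type array and not above background on the others).

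The ribosome biogenesis and cytosolic ribosomal protein lists were higher. Of 73 ribosome biogenesis genes, 46 rose and 1 fell, with a median difference of 1.17 (camera adjusted p = 1.86e-05, but adjusted p = 0.68 with an estimated correlation). UTP15 rose 9.57-fold, SSF1 8.87-fold, NOC2 8.65-fold and SOF1 8.09-fold. Of 129 measured cytosolic ribosomal protein genes, 33 rose and none fell, with a median of 0.77 (camera adjusted p = 1.86e-05, and adjusted p = 0.68 with an estimated correlation). RPL22B rose 5.78-fold, RPL26A 3.40-fold, RPS14B 3.08-fold and RPL36A 3.02-fold. Of the 13 RNA polymerase I subunits, 10 rose and none fell, with a median of 1.33, and the list did not pass (camera adjusted p = 0.0919). RPA43 rose 5.57-fold, RPC10 4.31-fold, RPA34 4.28-fold and RPC19 3.19-fold. Initiation and rDNA factors gave 5 rises among 16 (median 0.40, camera adjusted p = 0.305), led by RRN11 at least 6.96-fold. The median of this list was 0.05 after quantile normalization again. RNA polymerase III subunits gave 3 rises among 10 (median 0.89, camera adjusted p = 0.429), with RPC17 at 8.76-fold. Of 7 RNA polymerase II subunits, 2 rose and 1 fell (median 0.71, camera adjusted p = 0.610), with RPB9 up 7.37-fold and RPO21 down 4.33-fold. Mitochondrial ribosomal proteins had 1 rise and 4 falls among 68 (median -0.04, camera adjusted p = 0.0606), and translation factors 1 rise among 26 (median 0.20, camera adjusted p = 0.961), SUI3 at 2.00-fold. Its difference was 0.97 without replicate 2 of the arrays labelled RPA12 deletion and 0.92 after quantile normalization again, each under 2-fold. Poly-A spike-ins differed by -3.81, but they hold no yeast RNA, so their sign does not tell whether processing raised these lists.

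The lists of gluconeogenesis, the tricarboxylic acid cycle, β-oxidation, respiration and glycolysis were lower, with differing shares of genes that fell. For each of these 5 lists the adjusted p = 0.68 with an estimated correlation. Of 20 genes of gluconeogenesis and the glyoxylate cycle, 18 fell and none rose, with a median difference of -3.03 (camera adjusted p = 1.26e-04). FBP1, fructose-1,6-bisphosphatase, fell 18.1-fold, MLS1, malate synthase, 15.4-fold, JEN1, a lactate transporter, 14.3-fold, and SFC1 13.4-fold. Of 18 tricarboxylic acid cycle genes, 10 fell and none rose (median -1.13, camera adjusted p = 2.49e-04), with CIT3 down 10.1-fold and KGD1 4.41-fold. Of 17 peroxisomal β-oxidation genes, 8 fell and 1 rose (median -1.31, camera adjusted p = 0.0010), with POT1 down 17.5-fold and POX1 9.35-fold. The respiratory chain and ATP synthase had 7 falls and 1 rise among 37 (median -0.34, camera adjusted p = 0.0026): NDE2 fell 6.36-fold and COX5B, the hypoxic subunit isoform, rose 3.59-fold. CYC1 differed by -1.64 and did not pass (limma adjusted p = 0.0540). Glycolysis and fermentation had 5 falls among 18 (median -0.71, camera adjusted p = 2.49e-04), with ENO1 down 3.79-fold, TDH1 3.42-fold and PDC1 2.56-fold. Among 16 hexose transporters 3 rose and 4 fell (median 0.05, camera adjusted p = 0.969). HXT4 rose 13.7-fold and HXT3 13.0-fold. Poly-A spike-ins at -3.81, hybridization controls at -1.48 and ribosomal RNA probe sets at -1.74 were also lower. The sign of these controls does not tell whether processing lowered the lists.

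The general stress and stationary-phase lists were lower, while the other stress lists did not pass. Of 45 general stress genes, targets of Msn2 and Msn4, 19 fell and none rose, with a median of -0.86 (camera adjusted p = 5.13e-06, and adjusted p = 0.68 with an estimated correlation). The same controls, lower as well, do not tell whether processing brought about these falls. PHM7 fell 18.9-fold, XBP1 13.4-fold and RTN2 11.2-fold. Of 20 stationary-phase and quiescence genes, 11 fell and 1 rose (median -1.51, camera adjusted p = 0.0037, and adjusted p = 0.68 with an estimated correlation). SIP18 fell 20.1-fold, PIR3 13.5-fold and SPS100 13.2-fold. Heat shock and chaperone genes had 5 rises and 1 fall among 24 (median 0.42, camera adjusted p = 0.429), with HCH1 up 5.28-fold. Oxidative stress genes had 2 rises and 3 falls among 30 (median -0.05, camera adjusted p = 0.470), with CTA1, a peroxisomal catalase, down 10.3-fold and SRX1 up 4.65-fold. Unfolded protein response genes had 2 rises and 6 falls among 21 (median 0.22, camera adjusted p = 0.888), including EUG1 at 3.94-fold lower and ERO1 at 3.16-fold higher.

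**Figure D3:**
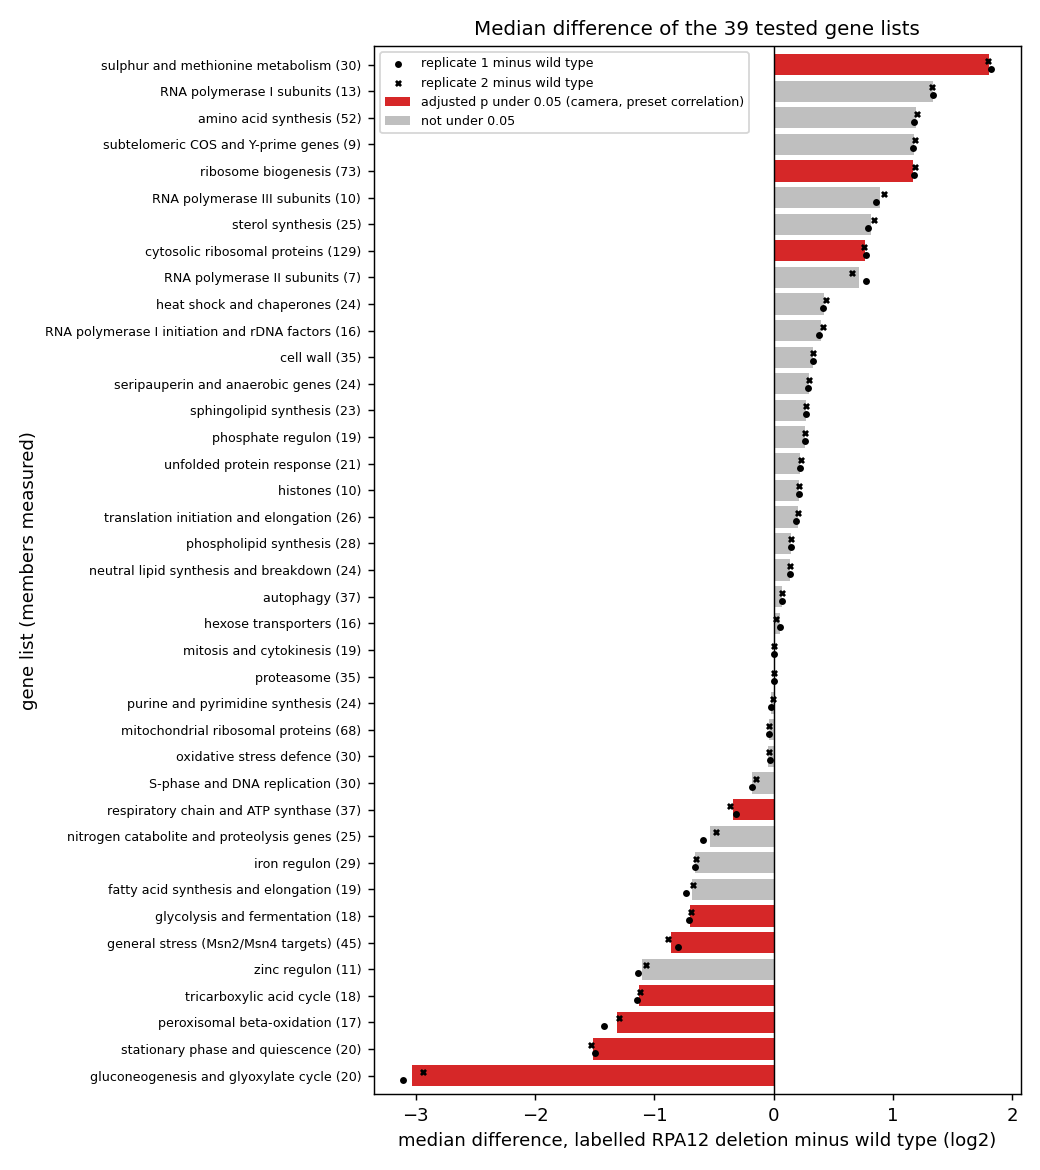
Median difference (log2, horizontal axis) of the 39 tested gene lists with the number of measured members, as bars, and the medians from each array labelled RPA12 deletion as symbols. Bars coloured red had camera adjusted p under 0.05 with the preset correlation, and none did with an estimated correlation; the sulphur list is highest at 1.81 and gluconeogenesis lowest at -3.03.

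The sulphur list was higher, and the amino acid synthesis list did not pass. Of 30 sulphur and methionine genes, 22 rose and 1 fell, with a median of 1.81 (camera adjusted p = 0.0147, and adjusted p = 0.68 with an estimated correlation). MET28, a regulator of these genes, rose at least 23.8-fold and SAM1 12.8-fold. This list holds MET17. Of 52 amino acid synthesis genes, 29 rose and 5 fell (median 1.19, camera adjusted p = 0.0610), with BAT1 up 12.4-fold and GDH3 down 13.7-fold. Purine and pyrimidine genes had 1 rise and 5 falls among 24 (median -0.02, camera adjusted p = 0.429), with SHM2 and URA2 down 3.41-fold and 3.38-fold.

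Lipid genes went in both directions, and no lipid list other than β-oxidation passed the main camera test. Fatty acid synthesis had 2 rises and 4 falls among 19 (median -0.68, camera adjusted p = 0.0610). Camera on ranks called this list lower. OLE1, the fatty acid desaturase, fell 19.7-fold, FAA4 6.42-fold and ACC1, acetyl-CoA carboxylase, 5.69-fold. Sterol synthesis had 10 rises and 1 fall among 25 (median 0.82, camera adjusted p = 0.255), with ERG5 up 6.31-fold, UPC2 6.09-fold, ERG4 5.77-fold and ERG11 2.89-fold. Sphingolipid synthesis had 8 rises and 1 fall among 23 (median 0.27, camera adjusted p = 0.807), with SUR2 up 6.24-fold. Phospholipid synthesis had 6 rises among 28 (median 0.15, camera adjusted p = 0.663), with INM1, inositol monophosphatase, up at least 19.2-fold from a wild-type value of 1.66, which is not above background. Neutral lipid genes had 7 rises and 5 falls among 24 (median 0.13, camera adjusted p = 0.888), with LDB16 up 7.53-fold, SCS3 7.05-fold and YEH1, a steryl ester hydrolase, 6.98-fold.

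Nutrient regulons did not pass as lists, though single members moved far. Of 29 iron regulon genes, 11 fell and 3 rose (median -0.66, camera adjusted p = 0.256), with SIT1 down 15.2-fold and FIT2 14.8-fold. Zinc regulon genes had 5 falls and 1 rise among 11 (median -1.10, camera adjusted p = 0.299), with ADH4 down 14.9-fold. Nitrogen catabolite genes had 8 falls and 5 rises among 25 (median -0.54, camera adjusted p = 0.0610). PUT4, a proline permease, fell 21.9-fold and GAP1, the general amino acid permease, 9.65-fold. Phosphate regulon genes had 5 rises and 1 fall among 19 (median 0.27, camera adjusted p = 0.0771), with GDE1 up 10.4-fold and PHO89 down 7.37-fold. Autophagy genes had 5 rises and 5 falls among 37 (median 0.07, camera adjusted p = 0.888).

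Cell cycle and surface genes were mixed. S-phase and replication genes had 7 falls and 3 rises among 30 (median -0.18, camera adjusted p = 0.0919), with POL2 down 5.41-fold and POL30 4.40-fold. CLN1, a G1 cyclin, was not above background at 1.39 ± 0.035 (SD, n = 2) against 4.03, at least 6.11-fold lower. The mitosis and cytokinesis list had 2 rises and 1 fall among 19 (median 0.00, camera adjusted p = 0.676), with CLN3 down 12.6-fold. CLN3, though held in this list, is also a G1 cyclin. Histones had 1 rise and 1 fall among 10 (median 0.21, camera adjusted p = 0.961). No proteasome gene among 35 was 2-fold apart (median 0.00, camera adjusted p = 0.429). Cell wall genes had 10 rises and 8 falls among 35 (median 0.33, camera adjusted p = 0.961), with PRM5 up 8.78-fold and SLT2, the cell integrity kinase, 6.73-fold. Seripauperin and anaerobic genes had 5 rises and 2 falls among 24 (median 0.30, camera adjusted p = 0.719), with ANB1 up 9.69-fold. Subtelomeric COS and Y-prime genes had 5 rises among 9 (median 1.17, camera adjusted p = 0.426), with COS7 up 10.2-fold.

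Of the 10 single genes measured, whose median was 0.03, RPA12 and MSN4 rose, MSN4 by 2.91-fold, and MSN2 differed by -1.34 and did not pass (limma adjusted p = 0.0995). ACT1 differed by -0.31, TAF10 by 0.31, UBC6 by -0.24, ALG9 by -0.50, TFC1 by -0.58, SPT15 by 0.77 and YAP6 by 0.76. Adjusted over the list alone, the counts of rises and falls were those given for all lists but mitosis and cytokinesis, where 1 gene rose in place of 2, and meiosis, where 3 fell in place of 4. For 11 of the 46 lists the sign of the median depends on the scaling, none of them called, and the largest of their medians was 0.30.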

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

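All tests in this part that weigh an explanation were chosen after the results they concern were seen. A reporter-gene control probe set, which the comparisons do not use, read 9.97 ± 0.049 (SD, n = 2) on the arrays labelled RPA12 deletion and 4.07 on the wild-type array, a difference of 5.90 on the log2 scale. It is given because its difference is the largest in size among 47 reporter-gene control probe sets. Of these, 1 was at least 2-fold higher and 1 at least 2-fold lower, with the brighter group above background. What its sequence encodes is not given in the sources used here. Of 3470 probe sets without a gene name here, 44 were at least 2-fold higher on the arrays labelled RPA12 deletion and above background there, and 88 were at least 2-fold lower.

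Strain and mating-type markers separated the arrays although the labels give all of them the same background. Within that background, where MET17 is deleted, neither exchanged groups nor a response to the loss of RPA12 can account for MET17, whose lower value on the arrays labelled RPA12 deletion was 9.36 against at most 2.42 among background probe sets, but this excludes nothing in cells of another background. Admixed cells of the labelled background would keep HMRA1 and LYS2 up, and the smaller of the bounds on their differences was -4.66. Whether α cells may stand in place of a cells there stays open. HMRA1 at background goes with them. So do the α-specific genes, of which 4 of 5 were at least 2-fold higher and none 2-fold lower (median difference 4.74). But 0 of the 7 a-specific genes were at background, and 2 were at least 2-fold higher against 1 lower. On the wild-type array 3 of 5 α-specific genes were above the background level. Of these, MF(ALPHA)2 at 2.01 and STE3 at 2.11 lay under the highest background probe set on that array, 3.37. Only SAG1, at 5.33, lay above that value. As SAG1 had signal on the wild-type array, a level above background does not settle whether α cells stand in place of a cells.

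BBC1 was without signal above background on the arrays labelled RPA12 deletion, where RPA12 had signal. A candidate explanation is that BBC1, and not RPA12, is disrupted in these cells: its neighbour MPS3 differed by -3.86, the fall of rank 31 among 5498 probe sets, as an insertion next to it could bring about, while the neighbour on the other side, PET130, was higher by 1.28. A broad repression with the growth state would take many other genes to background. Of the 1140 tested probe sets over 7 on the wild-type array, 2 (BBC1 and HMRA1) were at background on both other arrays. This count depends on the background level. NCA3 fell from 7.57 to 1.77 and 1.93, and TIS11 from 8.25 to 2.38 and 2.26. These values lie above the level but under the highest background probe set on those arrays, 2.42. Repression with the growth state still stays open, since a single gene can be repressed alone. It also stays open whether the RPA12 probe set, with a mean of 5.77 on these arrays, reads other transcripts or a part of the gene outside the deletion. An exchange of the groups on top of a difference in background stays open for RPA12, which was lower on the wild-type array, at 3.60, whose growth protocol names cells lacking RPA12, yet above background there.

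Lists of ribosome biogenesis and ribosomal proteins were called higher, and lists of general stress, stationary phase and respiratory carbon use lower, on the arrays labelled RPA12 deletion, none of them with an estimated correlation (adjusted p = 0.68). How far the cultures had gone into stationary phase was not tested, since the lists that would show it are the pattern itself, and it stays open. Separate processing of the arrays cannot be told apart from the group, with a median poly-A spike-in difference of -3.81. An effect of losing RPA12 cannot be told apart either, as RPA12 was higher by 2.16 where it is labelled absent and strain, processing and genotype go together.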

How the results depend on the processing

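The fits to unequal values and with a pooled variance, and for list medians centring and leaving out an array, were chosen after seeing the data, and the other settings before. No paired analysis was possible because the groups share fewer than 2 replicate numbers, with 1 wild-type array. No named gene past the threshold and no median of a called list changed sign. Probe sets called lower numbered 1634 and became 2654 with quantile normalization again, 2693 with median centring, and 983 when only unequal values were fitted, which tests fewer probe sets and also changes the variance prior. With treat against 1.5-fold, 1456 were higher and 625 lower, and with a 2-fold minimum 1310 and 562, by construction fewer. The cause of the scaling changes was not tested beyond the shift of the median. Lists called higher numbered 3 and lower 7. With an estimated correlation these were 0 and 0, with 0 of 39 at unadjusted p under 0.05 and a smallest adjusted p of 0.68. That setting rests on 1 residual degree of freedom and has little power. Fry called 21 higher and 18 lower, and 39 in either direction, and its sign opposed the list's median in 9 lists, stationary phase among them, and the cause was not tested. Quantile normalization again gave 6 lists higher and 10 lower, and ranks gave 3 higher and 8 lower, fatty acid synthesis being the list added. The 10 lists of the main test were called in both, and also above background and with the mean over probe sets. Leaving out each array labelled RPA12 deletion in turn leaves 1 array against 1, a value with no test: 1339 to 1343 probe sets were 2-fold higher, 601 to 609 lower, and RPA12 differed by 2.13 to 2.19. Leaving out the only wild-type array leaves no comparison. RPA12 differed by 1.54 after quantile normalization again. Signal near background limits the dimmest probe sets, which have bounds and not folds.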

Other observations

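The controls and the chromosomes were also examined. Ribosomal RNA probe sets of yeast, 17 in all, were lower on the arrays labelled RPA12 deletion, with a median difference of -1.74. The spike-ins at -3.81 and the hybridization controls at -1.48, which hold no yeast RNA, were lower too. The amount of ribosomal RNA can therefore not be read from these values. Replicate 1 minus replicate 2 of the arrays labelled RPA12 deletion had a median of 0.38 for ribosomal RNA and 0.35 for hybridization controls. Of 5 control transcripts whose 5' probe set was above background on every array, the 3' excess over the 5' end was larger on the arrays labelled RPA12 deletion for 4 and on the wild-type array for 1, and 2 more were left out. For ACT1 the excess was 2.02 and 2.35 against 1.69, and for TDH1 1.82 and 1.87 against 0.58. RIP1 was nearly equal, at 0.88 and 0.89 against 0.87. SPT15, the 1 that went the other way, had 2.26 and 2.34 against 3.67. These were not tested. By chromosome, the median difference ran from 0.00 for I to 0.38 for III, with XVI next at 0.32.

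Probe sets over 7 in one group and at or below background in the other were few. Dimmer cases are not counted here, among them MET28, PRM1 and INM1, which were higher, and LYS2, which was lower. Values just above the background level are not counted either, such as those of NCA3, which was lower. With a mean over 7 on the arrays labelled RPA12 deletion and at or below background on the wild-type array were 4 of 1225 probe sets, AGA1, HMLALPHA1, MET17 and MF(ALPHA)1.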
